A study of Mus musculus with 4 samples.

How the data were processed

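Total RNA of footpads from WT and Tabby mouse embryos at E15.5 was hybridised, per the labels, against a common reference of RNA from 11 cell lines pooled in equal parts. The 4 samples were labelled with Cy3 and the reference with Cy5 on every array, without dye exchange. The groups, WT and Tabby, were taken from the sample titles, which match the source names. The characteristic for the genetic modification differs from both for WT 2 and Tabby 2, and was not used for grouping. The labels do not say whether the numbers 1 and 2 pair samples across the groups, and they were not used in the main comparison. All 4 arrays lay on 1 slide and were scanned together (1 scan time), so no slide or scan could be used as a batch.

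The deposited scanner files hold, per the file headers, spot intensities from Agilent Feature Extraction 9.5.1.1, that is, mean pixel intensity and median local background of each spot in both channels. They also hold processed intensities, which per the file headers were background-subtracted and dye-normalised within each array, and a log10 ratio made by that software. The authors' deposited value table holds log10 values for 25164 of the probes. Its unit, channel and direction were worked out from the scanner values, matched by feature number. Each column correlated across probes with the log10 processed Cy3 intensity of its array (r = 0.998), and with that of Cy5 at r = 0.908 to 0.911. Column medians were 2.47, 2.48, 2.46 and 2.48 for WT 1, WT 2, Tabby 1 and Tabby 2. How the authors scaled these values between arrays and selected the probes is not given in the sources used here. For the called probe Z00016441-1 the authors' deposited table gives 0.43 and 0.90 in WT and 4.09 and 3.91 in Tabby.

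Mean signals were corrected with the normexp method (offset 50) from the median local background and normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. The log2 ratio is footpad over reference throughout. Spots marked as outliers, 2 to 9 per array, were left out, and repeated spots of a probe were averaged (7 probes had 5 spots each). Of 42006 probes, 31811 were kept because the Cy3 signal was well above background on at least 2 of the 4 arrays. Tabby and WT were compared with lmFit and eBayes (two-sided, Benjamini-Hochberg adjustment over all probes kept), with a threshold of 0.05 on the adjusted p. Levels per channel, used for the bound on a probe not above background and for the spread between arrays, were taken after Aquantile normalisation of the loess-corrected values. Such a bound is open to dye bias.

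The scanner files give probe IDs in place of gene names (0 of the probes have a name), 0 have a genome position, and 0 IDs matched the gene table used here (assembly GRCm38). The comparison was therefore made per probe in place of per gene. The 28 gene lists fixed before the data were examined, the values of Eda and its pathway, sex-linked genes and cell type markers, and the set tests are not analysed here. The design, the alternatives and the rule for named probes were also fixed before the data were examined. That rule takes up to 10 in each direction with no overlap between the groups, those past the threshold first by size of change and then those with the smallest unadjusted p. As the IDs carry no gene name, only the first 2 in each direction are printed.

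The fit was tested on simulated data: 20 sets of 31811 probes with the WT means of the real probes, variances drawn from the fitted prior (2.70 degrees of freedom) and 200 probes changed by known sizes. Among unchanged probes, 4.1 were called per set on average. A further 100 sets held 4 changed probes each, with 0.05 unchanged probes called per set. In all sets the noise was independent, with the same variance in both groups for each probe. The real Tabby arrays lay further apart than the WT arrays, so these rates need not hold for the real data. Alternatives covered the background correction, the normalisation within and between arrays, the Cy3 channel alone, the filter on dim probes, the variance model, a minimum fold change, the replicate number as a block, the authors' deposited table and the omission of each array. As precision, 16 pairs of kept probes with the same sequence under different IDs had a within-array SD of 0.085 in log2 ratio, and of 0.065 in the Tabby to WT difference.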

Results

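RNA from the footpads of mouse embryos at E15.5 (days of embryonic development) was measured on 4 two-colour Agilent arrays, 2 from wild-type (WT) embryos and 2 from Tabby embryos. Tabby is a mutation of Eda, the gene of the signalling protein ectodysplasin, and mice that lack ectodysplasin form no sweat glands. In the mouse, sweat glands form in the footpads. On every array the footpad RNA carried the dye Cy3 and a common reference, RNA pooled from 11 mouse cell lines, carried Cy5. The files pair none of the probes with a gene name, so the measurements are given by probe ID and by the sequence of the probe, which is 60 bases long. The strain is given as C57BL/6 for the samples. Both WT samples are described as male and both Tabby samples as mixed sex, so that sex and genotype differed together between the groups.

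The footpad signal was well above background for 31549 probes on the array of WT 1, 32365 on that of WT 2, 30164 on that of Tabby 1 and 31346 on that of Tabby 2, out of 42006 probes. For the reference the numbers lay between 30273 and 31314. Median Cy3 signals of the spots were 132.0 in WT 1, 146.9 in WT 2, 106.7 in Tabby 1 and 131.0 in Tabby 2, over median local backgrounds of 38 to 40. Saturation touched 1 spot in the Cy5 channel and none in Cy3. The number of arrays, 2 per group, limits the precision of every comparison. Nothing in the labels says whether the samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical.

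The comparison of Tabby with WT footpads asks which transcripts differed between the groups at E15.5, and it cannot separate genotype from sex. Transcript detected by a single probe, Z00016441-1, was higher in Tabby footpads past the threshold, and no probe was lower. Its sequence is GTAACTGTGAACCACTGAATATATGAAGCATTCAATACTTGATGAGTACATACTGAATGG. Its footpad signal was not well above background on either WT array and was well above background on both Tabby arrays. The log2 ratio of footpad to reference was -5.24 in WT 1 and -5.22 in WT 2, against 1.69 in Tabby 1 and 1.16 in Tabby 2. The group means were -5.23 ± 0.01 in WT and 1.42 ± 0.37 in Tabby (SD, n = 2 each). Both WT signals were at background, where the level depends on the offset of 50 in the background correction, so the SD of 0.01 does not measure agreement between the WT samples.

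With the WT signal bounded by background, the main processing put the transcript of Z00016441-1 at least 81.5-fold higher in Tabby than in WT. That bound is 6.35 on the log2 scale, above the differences fitted with median centring in place of loess (6.00) and with Cy3 alone after quantile normalisation (6.13). This bound sets the mean normalised Cy3 level of Tabby against, on each WT array, the higher of the probe's own level and the lowest level of any probe well above background. The fitted difference was 6.65 on the log2 scale (SE 0.20, limma, adjusted p = 0.0273). The SE and p rest in part on the WT values at background, whose spread the offset of 50 narrows. They therefore do not measure the spread between the WT samples for this probe. With Agilent's processed signals without loess, the SE was 0.59 and the adjusted p 0.522; with an offset of 16 in place of 50 they were 0.22 and 0.00523. The reference signal of the same probe was well above background on all 4 arrays, with processed Cy5 intensities of 4295, 4700, 3268 and 3843 in WT 1, WT 2, Tabby 1 and Tabby 2. The processed Cy3 intensities were 2.87 and 9.35 in WT and 10100 and 7873 in Tabby. The group labels differ in sex as well as genotype, and the call was lost in part of the alternative settings given in the closing part on processing. Without either WT array the adjusted p was 0.256 or 0.254.

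Among the other probes whose Tabby values both lay on one side of both WT values, the smallest unadjusted p-values belonged to probes that did not pass the threshold. Z00050081-1, with the sequence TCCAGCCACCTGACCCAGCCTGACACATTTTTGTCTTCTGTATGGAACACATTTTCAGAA, had mean log2 ratios of -1.26 ± 0.05 in WT and -0.57 ± 0.04 in Tabby (SD, n = 2 each). Its difference was 0.68 (SE 0.10, limma, adjusted p = 0.999). In the other direction, Z00025402-1, with the sequence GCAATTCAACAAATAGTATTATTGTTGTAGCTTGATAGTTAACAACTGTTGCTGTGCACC, had means of 1.33 ± 0.10 in WT and -0.31 ± 0.13 in Tabby. Its difference was -1.65 (SE 0.12, limma, adjusted p = 0.891). Its processed Cy3 intensity was 6106 and 7243 in the WT samples and 1793 and 2146 in the Tabby samples.

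Z00077432-1, with the sequence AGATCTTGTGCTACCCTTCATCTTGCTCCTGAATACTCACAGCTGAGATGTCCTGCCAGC, had means of 1.19 ± 0.01 in WT and -0.16 ± 0.14 in Tabby. Its difference was -1.34 (SE 0.12, limma, adjusted p = 0.891). The difference was -2.01 with Agilent's processed signals and -3.01 with the Cy3 channel alone scaled to the 75th percentile. The processed Cy5 intensity of the common reference was also lower at this probe on the Tabby arrays, 84.5 and 103.2 against 187.9 and 222.1 on the WT arrays. These 3 probes were chosen for the absence of overlap between the groups, and none passed the correction for the 31811 probes tested.

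**Figure D1:**
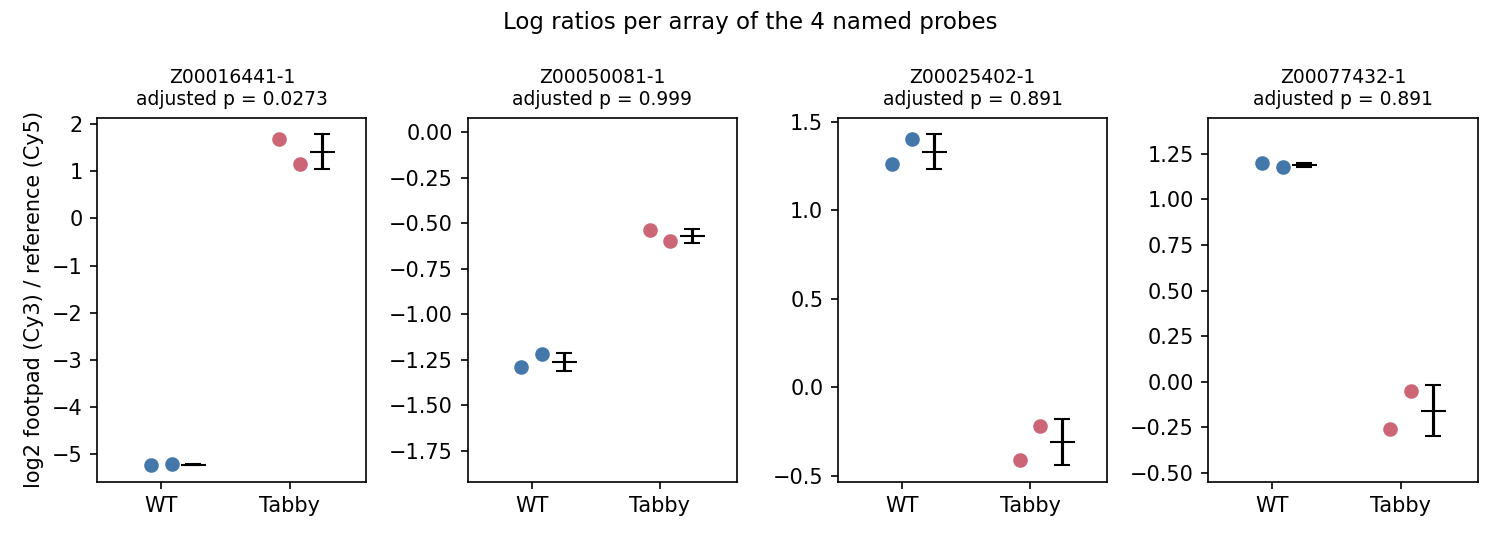
Log2 ratio of footpad (Cy3) to reference (Cy5) signal for 4 probes, each panel with its own vertical scale; points are single arrays, and the black marks are group means with SD (n = 2). Z00016441-1 sat at -5.24 and -5.22 in WT and at 1.69 and 1.16 in Tabby, while the differences of the other 3 probes did not pass the threshold.

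Over all 31811 probes, limma gave an unadjusted p under 0.05 for 1439 probes, 513 higher and 926 lower in Tabby, where 1591 would be drawn by chance if nothing differed. With median centring in place of loess the counts were 9 higher and 1990 lower. They were 14 and 136 without WT replicate 1, 114 and 261 without WT replicate 2, 5319 and 4273 without Tabby replicate 1, and 3125 and 5593 without Tabby replicate 2. The groups did not overlap for 34.0% of the probes, and chance gives 33.3%. At least 2-fold differences without overlap were found for 5 probes higher and 38 probes lower in Tabby. Counted with or without overlap, 64 probes differed at least 2-fold between the group means. Split by replicate number the count was 109, and split by the conflicting genetic modification characteristic it was 42. The difference between the groups was smaller than 1.5-fold for 98.6% of the probes, but the offset of 50 draws ratios of dim probes towards 1. In simulated data with the same number of probes and arrays and 200 changed probes per set, changes of 8-fold were called in 93.6% of cases, of 4-fold in 79.7%, of 2-fold in 6.4% and of 1.5-fold in 0.1%. With only 4 changed probes per set, 11% of the 8-fold changes and 0% of the 4-fold, 2-fold and 1.5-fold changes were called. The simulated noise was independent, with the same variance in both groups for each probe, whereas the real Tabby arrays lay further apart than the WT arrays. These rates therefore need not hold for the real data. Within the simulation, most changes of these sizes were not detectable after correction if few transcripts differed.

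The 2 Tabby samples differed from each other more than from the WT samples. The SD over probes of the difference in log2 ratio was 0.378 between Tabby 1 and Tabby 2 and 0.151 between WT 1 and WT 2, while the 4 pairs of a WT and a Tabby array gave 0.253 to 0.316. At least 2-fold differences separated Tabby 1 and Tabby 2 at 626 probes and WT 1 and WT 2 at 63 probes, of 31801 probes measured on all arrays.

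**Figure D2:**
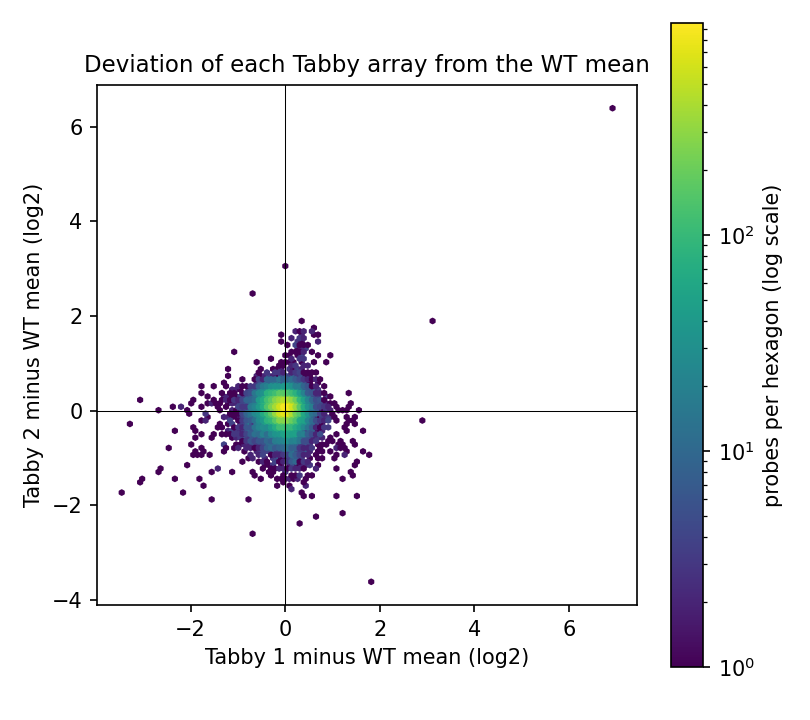
Deviation of Tabby 1 (horizontal) and Tabby 2 (vertical) from the mean of the WT arrays, in log2 units, with colour for the number of probes per hexagon on a log scale. Most probes lie around 0 on both axes, and the single point at the upper right is Z00016441-1, the only probe past the threshold.

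The spread was in the footpad channel. Between Tabby 1 and Tabby 2 the SD over probes of the log2 Cy3 signal difference was 0.402, against 0.164 between the WT arrays. The Cy5 signal of the common reference differed with an SD of 0.115 between the Tabby arrays and 0.089 between the WT arrays, and with 0.096 to 0.109 between arrays of different groups.

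**Figure D3:**
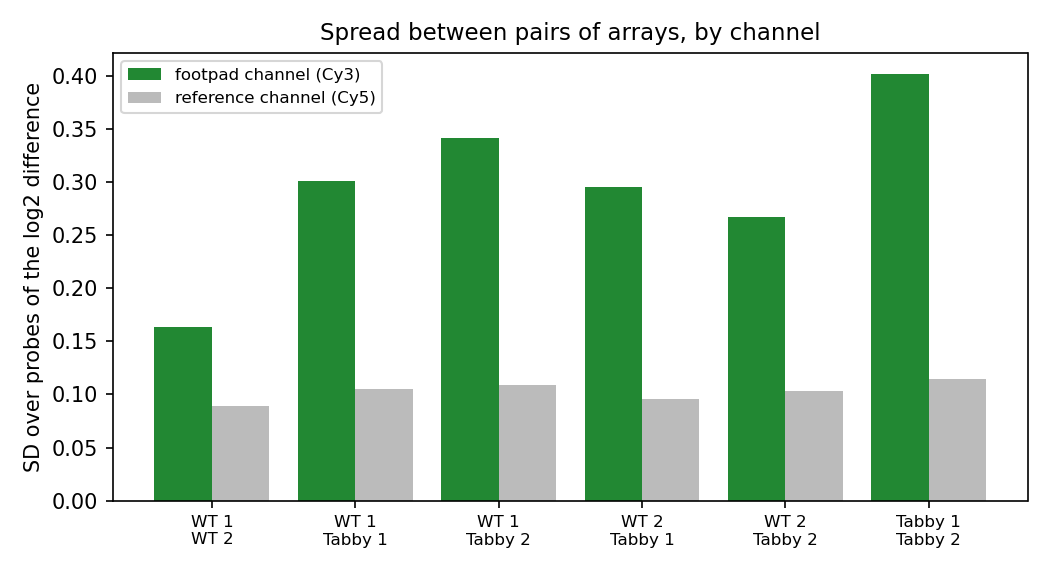
SD over 31801 probes of the log2 signal difference for each pair of arrays, in the footpad channel (Cy3, green) and the reference channel (Cy5, grey). The Tabby pair had the highest bar in the footpad channel (0.402) and the WT pair the lowest (0.164), while the reference bars lay between 0.089 and 0.115.

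Against the reference pool, 1525 probes (4.8%) were at least 4-fold brighter with footpad RNA on all 4 arrays and 819 probes (2.6%) at least 4-fold brighter with the reference. The ratio stayed within 2-fold on every array for 65.6% of the probes, a share that the offset of 50 raises among dim probes. The footpad signal was well above background on all 4 arrays, and the reference on none, for 1282 probes, and the reverse held for 776 probes. No test was made here, and since no array had the dyes exchanged, these ratios contain any dye effect of a probe. A constant dye effect cancels in the comparison of Tabby with WT.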

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

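All tests of explanations in this part were chosen after the result was seen. Outside the main measurement, 7 control probes had a median background-subtracted Cy3 signal above the brightest of 153 negative control spots on every array. The lowest of the 4 array medians was that of Tabby 1 for all 7. It was 8.20 for (+)E1A_r60_a107, 13.2 for (+)E1A_r60_a22, 30.1 for (+)eQC-39, 14.3 for DCP_22_0, 14.3 for DCP_22_2, 11.2 for DCP_22_6 and 8.26 for DCP_22_7. The medians of (+)E1A_r60_a107 were 37.9 in WT 1, 35.9 in WT 2 and 48.5 in Tabby 2. The brightest negative control spots read 5.74, 13.8, 3.73 and 10.7 on WT 1, WT 2, Tabby 1 and Tabby 2.

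Probe Z00016441-1 was the only probe called between the groups, with a footpad signal not well above background in WT and a strong one in Tabby. A defect of single spots would move both dyes, but the Cy5 difference between the groups at this probe was 0.035 of the Cy3 difference, which argues against that cause. A different sex of the groups stays open: 0 of the 4 pairs of a WT and a Tabby array have the same sex label, so sex and genotype cannot be told apart here. A transcript made in female but not in male tissue could give these values in male WT and mixed-sex Tabby samples, as could one repressed by Eda. Neither hypothesis was tested further, since the probe is not paired with a gene.

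Tabby 1 and Tabby 2 lay further apart than any other pair of arrays. Array or scanner noise would widen both channels, but the ratio of the Cy3 to the Cy5 SD in the Tabby pair was 1.89 times that in the WT pair. After the trend on GC content and signal level was removed, the SD of the Tabby pair was still 2.44 times that of the WT pair (2.51 times before), which argues against that trend as the whole cause. Exchanged labels of WT 2 and Tabby 2, which the conflicting characteristic raises, stay open. The Cy3 SD from WT 1 to Tabby 2 was 2.08 times that from WT 1 to WT 2. This distance cannot decide, because samples of a group need not lie closest over all probes. The Tabby pair itself lay further apart than every pair of a WT and a Tabby array. Differences in RNA preparation or labelling, in dissection, in exact stage or in the mix of sexes stay open, and no biological explanation was tested.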

How the results depend on the processing

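Of 17 alternative settings, 7 kept the count of 1 probe higher in Tabby and 15 kept the count of 0 lower. Both tallies include Aquantile normalisation and the minimum fold change of 1.5. These rest on the same fit as the main setting, so they could not change either count. The count of probes higher was 0 with Agilent's processed signals without loess, with Cy3 alone scaled to the 75th percentile, with Cy3 alone after quantile normalisation, without a filter on dim probes (adjusted p of Z00016441-1 0.0503), with both channels well above background on all arrays, and with the authors' deposited table. The strict filter removes Z00016441-1 by construction; for the others the cause was not tested. The unadjusted counts beside these zeros were 573, 401, 649, 839, 436 and 503 higher. Omitting each array in turn gave 0 to 1716 probes higher and 0 to 2357 lower. Both WT omissions gave 0 in each direction, while without Tabby replicate 1 the counts were 1716 and 2049, and without Tabby replicate 2 they were 1003 and 2357. There the lone Tabby sample is assumed to vary like the WT pair, so the wide spread between the Tabby samples no longer enters the test. With the replicate block, 1 probe was higher and 0 lower; the numbers are not said to pair the samples, and across probes the differences between replicates 1 and 2 correlated between the groups with r = 0.32. Aquantile normalisation leaves log ratios as they are.

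Z00016441-1 was higher in Tabby in all 15 alternatives that measured it, and past the threshold in 8 of them (adjusted p 7.07e-08 to 0.789). The fitted differences of 6.00 to 11.09 on the log2 scale are set by how each setting treats WT signals at background and are no measured sizes; the bound is 6.35, or 81.5-fold. The other 3 named probes kept their direction wherever measured (Z00077432-1 at -3.01 to -1.24) and passed the threshold only in the 2 settings without a Tabby array. Median centring in place of loess gave a median difference over all probes of -0.169 (log2), against 0.002 in the main setting, and 99.5% of its probes at an unadjusted p under 0.05 were lower in Tabby (1990, with 9 higher), against 64.4% with loess, so the surplus of lower probes depends on the scaling. Mean values over probes of a gene, set tests and Eda's probes could not be run without gene names. Dim probes limit what can be measured: 7276 probes were well above background in neither channel on any array.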

Other observations

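Among the 1525 probes at least 4-fold brighter with footpad than with reference RNA on every array, the probes at an unadjusted p under 0.05 were 80 lower and 13 higher in Tabby. With the Cy3 channel alone after quantile normalisation they were 101 lower and 36 higher. The median difference of all 1525 probes was -0.02 on the log2 scale. Among the 819 probes at least 4-fold brighter with the reference, the balance was the opposite, with 44 higher and 11 lower in Tabby and a median difference of 0.09. With the Cy3 channel alone these counts were 14 and 8, and the median difference was 0.02. Over all probes tested the numbers were 926 lower and 513 higher, and over the 20869 probes within 2-fold of the reference on every array 346 lower and 284 higher. Split by replicate number, the 1525 footpad-bright probes had 158 higher and 19 lower in the samples numbered 2 and a median difference of 0.16. Split by the conflicting genetic modification characteristic, 6 were higher and 25 lower in WT 2 and Tabby 1, with a median of -0.12. Of the 819 reference-bright probes, 17 were higher and 15 lower in the samples numbered 2. By the characteristic, 0 of them were higher and 2 lower in WT 2 and Tabby 1. With 2 arrays per group only 3 splits of the arrays exist, too few for a share under 0.05.

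The footpad signal was well above background on both WT arrays and neither Tabby array for 367 probes, and on both Tabby arrays but neither WT array for 14. Divided by replicate number, 338 probes were well above background only in the samples numbered 2 and 14 only in those numbered 1, and by the genetic modification characteristic the numbers were 72 and 56. Detection over all probes differed in the same way, from 30164 probes in Tabby 1 to 32365 in WT 2, with median Cy3 signals of 106.7 and 146.9. Over all probes tested, the split by replicate number gave 1983 probes at an unadjusted p under 0.05 and 0 past the threshold, against 1439 and 1 for genotype, and the split by the genetic modification characteristic gave 277 and 0.

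The probe with the widest difference between the Tabby samples, chosen after its values were seen, was Z00063945-1, with the sequence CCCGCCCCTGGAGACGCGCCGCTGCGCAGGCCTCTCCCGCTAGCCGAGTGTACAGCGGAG. Its log2 ratio was 3.79 in Tabby 1 and -1.65 in Tabby 2, a 43.5-fold difference, and 2.67 in WT 1 and 1.26 in WT 2. In 5 equal groups of probes from the dimmest to the brightest, the median absolute difference was 0.10, 0.177, 0.269, 0.291 and 0.266 for the Tabby pair. For the WT pair it was 0.076, 0.087, 0.092, 0.086 and 0.069.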
